A study of Rattus norvegicus with 18 samples.

How the data were processed

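The series holds 18 two-colour Agilent arrays of rat brain RNA. Per the labels, each array compares a pool of 3 WHP rats with a pool of 3 WLP rats in 1 of 3 brain areas, and the arrays form 9 pool pairs measured on 2 arrays each with the dyes swapped. The spot intensities, mean foreground and median local background brightness of both channels, were deposited as scanner output, neither background-corrected nor dye-normalized, per the file headers (Agilent Feature Extraction 10.10.1.1). The scanner's processed signal intensities in the same files are background-subtracted and dye-normalized, per the file headers. The deposited value table gives 1 log2 ratio per probe and array. Set against log2 ratios of the scanner's processed signals, its sign is that of WHP over WLP on all 18 arrays, its array medians lie between -0.011 and 0.021, and its normalization is unstated. On 16 arrays it correlates with the scanner's ratios at 0.92 or more, and on the first arrays of prefrontal pool pair 1 and hippocampus pool pair 3 at 0.62 and 0.76, with slopes of 0.33 and 0.52.

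Each array holds 45018 spots, 1639 of them controls, and 41012 distinct probes. Probes were named through their accession in the given RefSeq gene table (17561 probes by their own accession, 414 by another listed accession) or the file's symbol (2844 current, 518 replaced through a synonym, 95 kept), which left 19580 probes unnamed. Symbols that are only locus placeholders were not named. Probe coordinates are those of the files, on the rn4 build. The depth of an array is its signal over background: 28670 to 38080 spots were well above background in green and 31207 to 38173 in red.

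Before the data were examined, the grouping, the tests, the gene lists, the rule for named genes and the alternatives were fixed, except those said to be chosen after seeing the data. Signals were background-corrected with limma 3.58.1 in R 4.3.3 (normexp, offset 50), normalized within each array by loess with control spots at weight 0, and cleared of control spots and spots the scanner marks as non-uniform. The offset adds 50 to both channels and so pulls the ratios of dim spots towards 0. Ratios were turned to WHP over WLP by the dyes in the labels, spots of 1 probe were averaged, and the 2 dye-swapped arrays of a pool pair were averaged to 1 replicate. A dye effect cancels in that mean. It does not cancel in the alternatives with a single dye orientation, where it cannot be told apart from a strain difference. A probe counted as detected in an area when it was well above background in the channel of at least 1 strain on at least 4 of that strain's 6 arrays.

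Strain differences were tested with lmFit and eBayes over the 9 pool-pair ratios, with 1 coefficient per area, so that the areas share 1 estimate of the spread (6 residual and 2.46 prior degrees of freedom). The tests were each area against 0, the mean of the 3 areas over probes detected in all of them, and the 3 differences between areas, two-sided, with Benjamini-Hochberg adjustment over the detected probes and a threshold of 0.05. Standard errors are moderated. Shared calls were set against the product of the areas' call numbers in the same direction over the probes detected in both areas. The labels call the 3 pool pairs of an area biological replicates and do not say whether pools of different areas came from the same rats.

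The 33 gene lists were tested with camera (preset correlation 0.01) in each area, with 1 probe per gene, the brightest over all arrays among those detected, and Benjamini-Hochberg adjustment over the 99 tests. The tests were repeated with an estimated correlation and with fry, which asks whether a list's genes move on balance 1 way and does not compare the list with other genes. Lists needed at least 5 measured genes. Differences of list shifts between areas were tested in the same way. Brain area markers were compared between arrays without a test.

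Named genes follow a rule with 1 probe per gene, the brightest detected. In each area these are up to 10 genes with the largest positive and 10 with the largest negative ratio among those past the test with the same sign in all 3 pool pairs, and up to 4 members of each list that pass. For the mean they are the genes called with the same sign in all 3 areas, to which members of the lists that passed in the mean were added after seeing the data. For each difference between areas, where none passes, they are drawn from the 5 smallest p-values in each direction. Every named probe was above background on some arrays of both strains, so no bound was needed. For 1 gene of the prefrontal medial cortex that the rule picks, the result is not reported here.

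The arrays lie on 5 slides scanned in 2 sessions. Slides 1 to 3 hold nucleus accumbens and prefrontal pool pairs of the same number, and slides 4 and 5 hold the hippocampus, scanned second. Median signals were 78.2 to 100 in green in the first session and 155 to 209 in the second. Dye-swapped arrays of a pool pair correlated across probes at 0.60, 0.71 and 0.05 in the nucleus accumbens, 0.57, 0.67 and 0.57 in the prefrontal medial cortex, and 0.65, -0.01 and 0.31 in the hippocampus.

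The local background of a few spots lay furthest above the rest on 2 arrays: up to 33195 in green and 15547 in red on the first array of prefrontal pair 1 (medians 31 and 40), and up to 28300 in red on the first array of hippocampus pair 3 (median 39). There normexp lifted the median log2 intensity to 9.09 and 8.75 and squeezed the ratios. The fixed processing was kept, and an alternative chosen after seeing the data gave every spot whose local background exceeded 2 times the median of its array and channel that median, which brought these medians to 6.97 and 7.76. Other arrays had smaller outliers over that limit. Red backgrounds reached 1032 on the second array of hippocampus pair 1 (median 40.5) and 547 on the first array of nucleus accumbens pair 2 (median 39).

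Set beside this were the scanner's processed signals, no background subtraction, scaling of intensities between arrays, no or a stricter detection filter, saturated spots left out, the deposited value table, each area fitted alone, all 18 arrays entered singly with a dye covariate and pool pair as a random block, each dye orientation alone, the replicate number as a block, slide as a random block, eBayes with a trend over mean intensity and robust, a log2 ratio of at least 1, 1 probe per gene, the mean over a gene's probes for the lists, and each pool pair left out in turn. Chosen after seeing the data were the replaced local backgrounds, population outlier spots left out, the 2 pool pairs with uncorrelated dye-swapped arrays (nucleus accumbens 3 and hippocampus 2) left out, the first scan session alone with and without slide as a block, and the meninges and choroid plexus lists as covariates. Where the alternatives that a gene passed are counted, genes under 1 in size must fail the limit of 1. Scaling between arrays and leaving out saturated spots could not change a call, so such counts hold passes given in advance.

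The tests were tried on simulated ratios with the real residual spread and probes changed by known amounts. At a log2 ratio of 0.5 limma recovered 76.1% of 67 changed probes in the nucleus accumbens, 68.7% in the prefrontal medial cortex, 61.2% in the hippocampus and 91.0% in the mean of the areas, and at 1 it recovered 97.0% in each area and 100% in the mean. Of 186, 186, 178 and 213 calls 4, 10, 6 and 19 were wrong. A list of 52 genes shifted by 0.3 was called and 0 of 98 other lists. Simulated probes vary independently, which the real genes of several lists did not. In the nucleus accumbens the estimated correlation was 0.90 for meninges markers, 0.30 for ribosomal proteins and 0.02 for GABA signalling, against the preset 0.01. The simulation thus gives no error rate for the list tests on the real data. Its recovered shares and wrong calls for single probes likewise hold for independent probes, and give no error rate for the real ones.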

Results

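The series compared the brains of 2 rat strains bred for opposite ethanol preference, the high-preferring WHP and the low-preferring WLP strain, in male rats that had never had alcohol. Gene expression was measured on 18 two-colour Agilent arrays in 3 brain areas: the nucleus accumbens, the prefrontal medial cortex and the hippocampus. Each array carried RNA of 1 WHP pool in 1 dye and RNA of 1 WLP pool in the other, each pool holding equal RNA from 3 rats. A second array with the dyes swapped repeated every pair of pools, so each area had 3 pool pairs on 6 arrays and n = 3. The median spot signal lay between 78.2 and 209 in green (Cy3) and between 133 and 303 in red (Cy5), and 28670 to 38080 spots were well above background in green and 31207 to 38173 in red. The number of pool pairs limits the precision. All values below are log2 ratios of WHP over WLP, so that a positive value means more signal from the WHP pool. A sequence variant under a probe could give such a difference without a difference in RNA level, a point taken up further below.

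Genes that mark each brain area were read first as a check of the labels. Striatum markers (20 genes such as Drd1 and Ppp1r1b) lay 2.56 ± 0.51 log2 units above the array median in the nucleus accumbens (SD over 6 arrays) and 0.34 ± 0.13 in the hippocampus. In the prefrontal medial cortex they lay 2.54 ± 0.66 above it, about the level of the nucleus accumbens. Cortex markers averaged 2.55 ± 0.62 in the prefrontal medial cortex, 1.96 ± 0.23 in the hippocampus and 0.92 ± 0.29 in the nucleus accumbens. Hippocampus markers averaged 2.05 ± 0.23 in the hippocampus, against 1.03 ± 0.37 and 0.96 ± 0.23 in the prefrontal medial cortex and the nucleus accumbens. The arrays labelled prefrontal medial cortex thus carried cortical and striatal marker signal together.

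**Figure D1:**
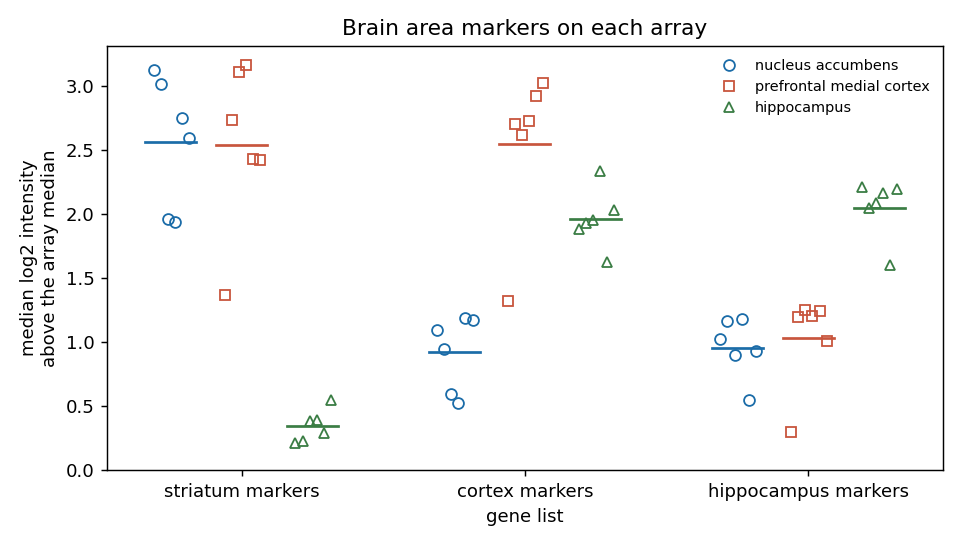
Median log2 intensity of 3 fixed marker lists above the median of each array, with 1 symbol per array and a line at the mean of the 6 arrays of an area. Striatum markers are high in the nucleus accumbens and the prefrontal medial cortex (means 2.56 and 2.54) and low in the hippocampus (0.34), and the lowest prefrontal array (1.37) is 1 of the 2 arrays with the largest outlying local backgrounds.

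In the nucleus accumbens, a part of the ventral striatum with a known role in reward, Tac4 and an olfactory receptor gene differed most between the strains among the named genes. Tac4, which encodes tachykinin peptides, was 3.74-fold higher in WHP (log2 1.90 ± 0.15, moderated SE, n = 3 pool pairs, adjusted p = 0.0039), and the olfactory receptor gene Or5b123b was 4.54-fold lower (log2 -2.18 ± 0.23, adjusted p = 0.013). Grem1, a secreted antagonist of bone morphogenetic proteins, was 1.93-fold higher (0.95 ± 0.14). The DNA primase subunit Prim1 (0.63 ± 0.06), the secreted phospholipase Pla2g12a (0.61 ± 0.06), the haem synthesis enzyme Uros (0.47 ± 0.05), Gnpnat1 of the hexosamine pathway (0.47 ± 0.05), the lipid kinase Pik3c3 (0.32 ± 0.05) and Klhdc2 (0.30 ± 0.04) were also higher. Lower in WHP were the netrin receptor Unc5d (-1.07 ± 0.14), the membrane skeleton protein Epb41l3 (-1.0 ± 0.13), the cyclic-AMP-regulated Arpp21 (-0.79 ± 0.09), the peptide gene Apln (-0.54 ± 0.08) and the FGF receptor-like Fgfrl1 (-0.50 ± 0.05). Also lower were Trim16 (-1.29 ± 0.17), the interferon-induced Mx2 (-0.59 ± 0.06), the striatal transcription factor Foxp1 (-0.54 ± 0.06), the mitochondrial ribosomal gene Mrpl52 (-0.57 ± 0.08), the ribosomal gene Rpl38 (-0.38 ± 0.04) and Maob, which breaks down dopamine (-0.38 ± 0.04). Their adjusted p ranged up to 0.048, and each had the same sign in 3 of 3 pool pairs. A second probe of Trim16 stood at -0.03, that of Unc5d at -0.07, and those of Arpp21 at -0.12 and 0.06, that of Grem1 at 0.28 and that of Apln at -0.43, none past the test, while the second probe of Prim1 passed at 0.87. With the scanner's processed signals Uros stood at 1.13, Or5b123b at -3.51, Trim16 at -2.73 and Mx2 at -1.16. Grem1 and Pik3c3 each passed in 10 of 31 alternatives, Apln in 11 and Klhdc2 and Mrpl52 in 14.

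In total 76 of 30216 detected probes passed limma's test at an adjusted p under 0.05, 41 of them higher and 35 lower in WHP, and 4923 had an unadjusted p under 0.05. They stood for 27 named genes, 8 higher and 19 lower by the brightest probe of each gene. The count rests on single pool pairs and on the spread shared with the other areas: it was 725, 132 and 23 without nucleus accumbens pair 1, 2 or 3, 148, 45 and 47 without prefrontal pair 1, 2 or 3, and 32, 31 and 30 without hippocampus pair 1, 2 or 3. It fell to 3 with the area fitted alone, to 5 with the first scan session alone (nucleus accumbens and prefrontal medial cortex), to 1 with slide as a block in that session, and to 2 without the pairs whose dye-swapped arrays were uncorrelated. With all 18 arrays entered singly it was 807, on the arrays with WHP in Cy5 or Cy3 alone 124 and 14, with the replicate number as a block 11, with a trend and robust variances 116, with 1 probe per gene 24 and with meninges and choroid plexus covariates 4. Counts from a single dye orientation, here and below, can mix dye and strain differences.

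Gene groups shifted in the nucleus accumbens in 6 of 33 fixed lists by camera with a preset correlation. Striatum markers were lower in WHP, with a median of -0.48 over 19 measured genes and medians of -0.25, -0.69 and -0.06 in the 3 pool pairs (adjusted p = 2.66e-06, 0.928 with an estimated correlation), and the median was -0.26 without pair 2. Of these 19 genes 1 (Foxp1) fell past the test over all probes, and 7 fell adjusted over the list alone. Both arrays of pair 2 had the lowest striatum marker level of the area. They stood 1.96 and 1.94 log2 units above the array median, against 2.59 to 3.13 on the other arrays. For this list, unequal tissue in the pools of that pair cannot be told apart from a strain difference. Astrocyte markers had a median of -0.13 (15 genes, 13 negative, adjusted p = 4.31e-04, 0.928 with an estimated correlation), with 0 past the test over all probes and 5 lower adjusted over the list alone. Glutamate receptors and transporters (median -0.08, 27 of 37 genes negative), GABA signalling genes (-0.06, 20 of 26 negative) and ribosomal proteins (-0.04, 34 of 52 negative) had adjusted p of 0.020, 0.038 and 0.0055, each 0.928 with an estimated correlation. Within them Rpl38 was the 1 gene past the test over all probes. Glutamate genes had pool pair medians of -0.07, -0.08 and -0.12, and the list's median was -0.021 without pair 2 and -0.13 without pair 1. The ribosomal median was -0.021 without pair 3 and -0.065 without pair 1. Meninges and fibroblast markers went the other way, with a median of 0.85 over 15 genes (adjusted p = 1.41e-04, 0.928 with an estimated correlation), but the pool pairs stood at 1.00, 2.48 and -0.77, and the median was 0.23 without pair 2 and 1.60 without pair 3. Dopamine signalling genes had a median of -0.04 and an adjusted p of 0.18, with Maob as the 1 of 16 members past the test.

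In the prefrontal medial cortex the same tachykinin and olfactory receptor genes led among the named genes. Tac4 was 3.79-fold higher in WHP (1.92 ± 0.15, adjusted p = 0.0059) and Or5b123b 6.18-fold lower (-2.63 ± 0.23, adjusted p = 0.0086). Prim1 (0.65 ± 0.06), Pla2g12a (0.61 ± 0.06), the galactosyltransferase B3galt2 (0.55 ± 0.06), Uros (0.48 ± 0.05) and Gnpnat1 (0.45 ± 0.05) were higher as well. The mitochondrial ribosomal genes Mrpl52 (-0.58 ± 0.08) and Mrpl4 (-0.40 ± 0.05), Rpl38 (-0.46 ± 0.04), Fgfrl1 (-0.41 ± 0.05) and Cpne5 (-0.28 ± 0.03) were lower. Each of these genes kept its sign in 3 of 3 pool pairs, with adjusted p up to 0.048. With the scanner's processed signals Uros stood at 1.17 and Or5b123b at -3.97. Mrpl4 was -0.20 on the arrays with WHP in Cy3 and Cpne5 -0.17 on those with WHP in Cy5. Cpne5 passed in 10 of 31 alternatives, Mrpl4 in 11, Fgfrl1 in 12 and B3galt2 in 14.

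These genes came from 26 of 28740 probes past limma's test, 18 higher and 8 lower, with 2430 at an unadjusted p under 0.05. The count was 23, 2 and 1 without prefrontal pair 1, 2 or 3, 15 without nucleus accumbens pair 1, and 14, 11 and 10 without hippocampus pair 1, 2 or 3. It was 53 (32 higher, 21 lower, 25 shared with the 26) with outlying local backgrounds replaced, a choice made after seeing the data, and 1 with the area or the first scan session fitted alone, slide as a block or not. It was 71 with the scanner's processed signals, 62 without background subtraction, 145 with all 18 arrays entered singly, 70 and 2 with WHP in Cy5 or Cy3 alone, 3 with the replicate number as a block, 13 with 1 probe per gene, 8 without the pairs whose dye-swapped arrays were uncorrelated and 7 with the covariates. Pool pair 1 ran against pair 2 across probes (r = -0.29, where probes are not independent replicates), and the same-dye arrays of these pairs correlated at -0.21 and -0.29.

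In this area 5 of the 33 lists shifted by camera. Astrocyte markers were lower in WHP with a median of -0.18, 15 of 15 genes negative and pool pair medians of -0.29, -0.08 and -0.14 (adjusted p = 5.18e-07, 0.928 with an estimated correlation). The median was -0.081 without pair 1, and 5 of them fell adjusted over the list alone, 0 over all probes. Cholesterol synthesis genes (median -0.08, 15 of 21 negative, adjusted p = 0.0044) and blood cell markers (-0.08, 7 of 8 negative, adjusted p = 0.0043) were lower, each at 0.928 with an estimated correlation. Their pool pair medians were -0.005, -0.20 and -0.09 for cholesterol synthesis and -0.05, -0.34 and -0.09 for blood cells. The cholesterol median was -0.13 without pair 1, and the blood cell median -0.17 without pair 3 and -0.20 with the scanner's processed signals. Ribosomal proteins had a median of -0.03 (adjusted p = 0.037, 0.928 with an estimated correlation) that turned to 0.030 without pool pair 1. Ependyma and choroid plexus markers had a median of 0.49 over 14 genes (adjusted p = 0.023, 0.928 with an estimated correlation), with pool pairs at -0.45, 1.79 and 0.09, and the median was -0.10 without pair 2. Striatum markers had opposite medians in the pool pairs here, at -0.69 in pair 1 and 0.34 and 0.28 in pairs 2 and 3.

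In the hippocampus the cartilage and vessel growth regulator Cnmd was 4.10-fold higher in WHP (2.04 ± 0.23, adjusted p = 0.015). Tac4 was 2.64-fold higher (1.40 ± 0.15, adjusted p = 0.0106) and Or5b123b 6.93-fold lower (-2.79 ± 0.23, adjusted p = 0.0051). The transcription factor Zeb2 (0.83 ± 0.09), Cml3 (0.79 ± 0.09), Pla2g12a (0.59 ± 0.06), Prim1 (0.53 ± 0.06), the sulfotransferase Sult1c2a (0.52 ± 0.06), Uros (0.49 ± 0.05), the kinase Hunk (0.33 ± 0.04) and the cap-binding factor Eif4e3 (0.32 ± 0.05) were higher. Sult1c2a was well above background on 6 of 6 WHP channels and 4 of 6 WLP channels. Lower in WHP were Epb41l3 (-1.06 ± 0.13), Unc5d (-1.0 ± 0.14), the endosomal adaptor Appl1 (-0.85 ± 0.11), the olfactory receptor gene Or10j3b (-0.77 ± 0.06), Mx2 (-0.57 ± 0.06), the coatomer subunit Copg2 (-0.56 ± 0.08), Mrpl52 (-0.51 ± 0.08), Mrpl4 (-0.43 ± 0.05), Cby2 (-0.39 ± 0.05) and Rpl38 (-0.32 ± 0.04). Each kept its sign in 3 of 3 pool pairs, with adjusted p up to 0.046. The other probes of Unc5d (0.03), Appl1 (-0.04 and -0.02), Copg2 (-0.01 and 0.11), Sult1c2a (0.09) and Eif4e3 (0.10 and 0.15) did not pass. With the scanner's processed signals Sult1c2a stood at 1.53, Uros at 0.76, Or10j3b at -1.23 and Mx2 at -1.13. On the arrays with WHP in Cy5 alone Zeb2 was 0.49, Uros 0.31, Hunk 0.20 and Rpl38 -0.16. Eif4e3 passed in 7 of 29 alternatives, Copg2 in 9 and Cby2 in 14.

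In the hippocampus 87 of 34749 probes passed limma's test, 51 higher and 36 lower, with 2320 at an unadjusted p under 0.05. The count was 28, 9 and 9 without hippocampus pair 1, 2 or 3 and 55 and 53 without prefrontal pair 2 or 3. It was 19 with the area fitted alone, 21 (13 higher, 8 lower) with the scanner's processed signals and 2 without the pairs whose dye-swapped arrays were uncorrelated. It was 26 with the deposited value table, 357 with all 18 arrays entered singly, 19 with the replicate number as a block or with 1 probe per gene and 10 with the covariates.

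Of the 33 lists 11 shifted in the hippocampus. Ribosomal proteins were higher in WHP, with 49 of 52 genes positive, a median of 0.10 and pool pairs at 0.09, 0.07 and 0.11 (adjusted p = 2.38e-12, 0.928 with an estimated correlation), although Rpl38, the 1 member past the test, was lower. Oligodendrocyte and myelin markers were higher (median 0.29, 19 of 19 positive, pairs 0.32, 0.23 and 0.13, adjusted p = 2.70e-05), and so were major histocompatibility complex and antigen presentation genes (0.22, 24 of 32 positive, pairs 0.29, 0.11 and 0.10, adjusted p = 1.09e-05) and interferon response genes (0.06, 23 of 28 positive, adjusted p = 0.037), among which Mx2 fell. For these 3 lists adjusted p = 0.928 with an estimated correlation. Without pair 1 the histocompatibility median was 0.10 and the interferon median 0.010. The interferon median was 0.20 in pair 1, 0.0012 in pair 2 and 0.011 in pair 3, and this list passed in 12 of 17 alternatives. Ependyma and choroid plexus markers (0.68, pairs 1.43, 0.14 and 0.47, adjusted p = 2.40e-06) and meninges and fibroblast markers (0.37, pairs 0.93, -0.13 and 0.33, adjusted p = 0.028) were higher beside them, each at 0.928 with an estimated correlation, and their medians were 0.30 and 0.18 without pair 1. Lower lists were GABA signalling (-0.06, 20 of 27 negative, adjusted p = 0.0045), neuron markers (-0.09, adjusted p = 0.012), cholesterol synthesis (-0.06, adjusted p = 0.037), striatum markers (-0.21, adjusted p = 0.0044) and thalamus, hypothalamus and septum markers (-0.11, adjusted p = 0.046), each at 0.928 with an estimated correlation. The neuron median was -0.018 without pair 3. Both signs occurred among the pool pairs for neuron markers (-0.10, 0.05 and -0.20), striatum markers (0.01, -0.24 and -0.34) and the thalamus list (0.07, -0.21 and -0.12), and the last passed in 9 of 17 alternatives. With fry 0 of the 99 list tests passed (lowest adjusted p 0.39). Over the list alone, 4 histocompatibility genes were higher and 1 lower, and 1 GABA gene was lower.

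**Figure D2:**
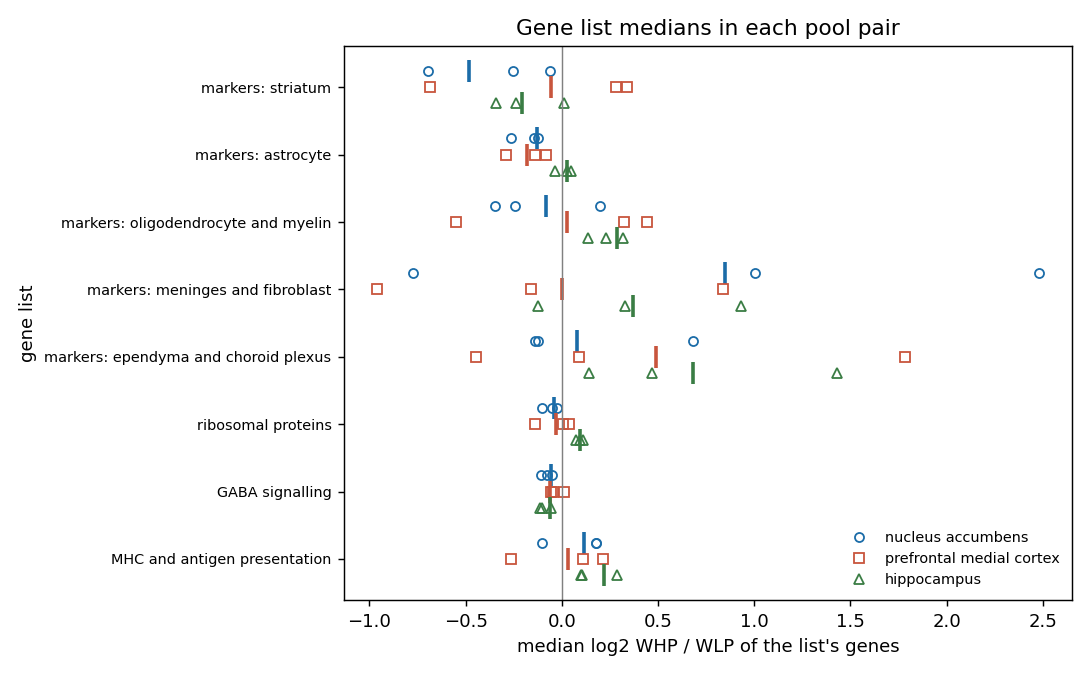
Median log2 ratio of WHP over WLP of 8 fixed gene lists, with 1 symbol per pool pair and a bar at the median of the area's fitted ratios. Meninges markers run from -0.96 to 2.48 and choroid plexus markers from -0.45 to 1.79 across pool pairs, while ribosomal proteins stay between -0.14 and 0.11.

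The mean over the 3 areas was tested against 0, which a difference in 1 area can also pass. The labels do not say whether pools of different areas came from the same rats. If they did, the 9 pool pairs are not independent and the standard errors below may be too small. Tac4 was 3.35-fold higher in WHP (1.74 ± 0.09, n = 9 pool pairs, adjusted p = 8.02e-05) and Or5b123b 5.79-fold lower (-2.53 ± 0.13, adjusted p = 1.12e-04). Prim1 (0.60 ± 0.03), Pla2g12a (0.60 ± 0.04) and Uros (0.48 ± 0.03) rose, and Mrpl52 (-0.55 ± 0.04) and Rpl38 (-0.39 ± 0.02) fell, each with its sign in 9 of 9 pool pairs. These 7 genes passed in every area, Mrpl52 least firmly. It passed in 9 of 31 alternatives in the prefrontal medial cortex and 9 of 29 in the hippocampus. Rpl38, also under 1 in size, passed in 21 of 31 and 18 of 29. Mrpl52 passed in no area with outlying local backgrounds replaced (adjusted p = 0.12, 0.096 and 0.19). In the mean Uros was 1.02 with the scanner's processed signals. On the rn4 build the Tac4 probe lies on chromosome 10 at 83953767 to 83953826, the Or5b123b probe on chromosome 1 at 216310307 to 216310366, the Prim1 probe on chromosome 7 at 1321717 to 1321776 and the Pla2g12a probe on chromosome 2 at 227347989 to 227348048. The Uros probe spans 193188294 to 193189266 on chromosome 1, the Mrpl52 probe 32491804 to 32491863 on chromosome 15 and the Rpl38 probe 158404762 to 158404821 on chromosome 3.

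**Figure D3:**
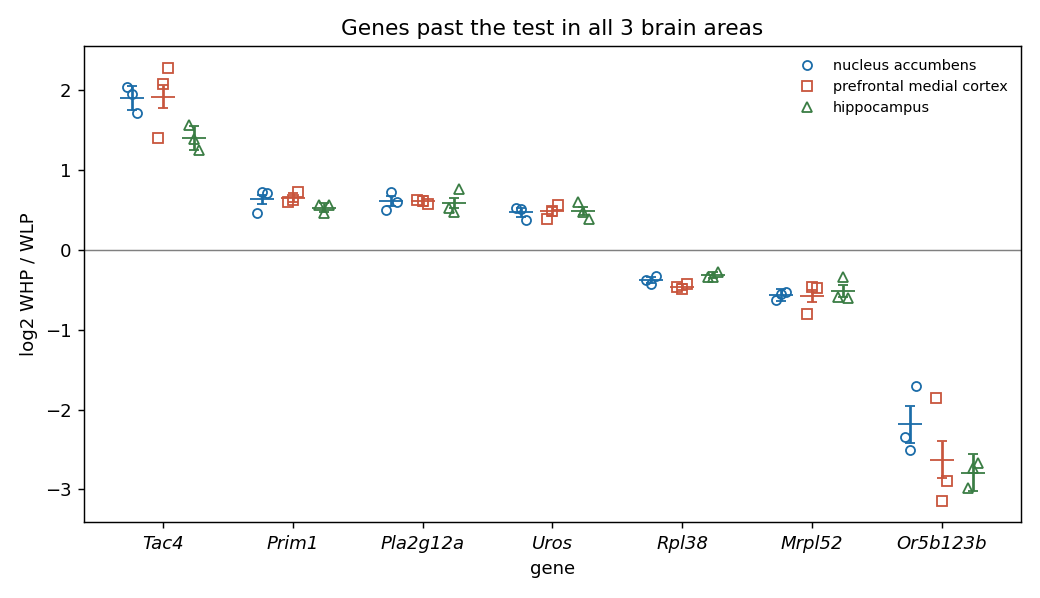
Log2 ratio of WHP over WLP of the 7 named genes past the test in all 3 areas, with 1 open symbol per pool pair and a bar at the area's mean with its moderated standard error. All 9 pool pairs of a gene lie on 1 side of 0, from 1.25 to 2.28 for Tac4 and from -3.14 to -1.71 for Or5b123b.

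Several members of the neurotransmitter and immune lists passed in the mean of the areas. Of 25 GABA signalling genes 2 fell and 0 rose: the receptor subunits Gabra4 (-0.66 ± 0.10, adjusted p = 0.012) and Gabrg1 (-0.32 ± 0.07, adjusted p = 0.041), both lower in 9 of 9 pool pairs, with 4 lower adjusted over the list alone. Of 15 dopamine signalling genes the adenylyl cyclase Adcy5 (-0.31 ± 0.06, adjusted p = 0.040) and Maob (-0.15 ± 0.03, adjusted p = 0.022) fell, lower in 8 and 6 of 9 pool pairs. Of 26 interferon response genes Irf7 (0.36 ± 0.06) and Ifi27 (0.29 ± 0.05) rose and Mx2 (-0.52 ± 0.04) fell. Of 29 histocompatibility and antigen presentation genes RT1-T24-1 (0.35 ± 0.06) and RT1-M3-1 (0.24 ± 0.04) rose and RT1-CE3 (-0.43 ± 0.08) fell, and 7 were higher and 1 lower adjusted over the list alone. Among striatum markers Adcy5, which is on the dopamine list too, Meis2 (-0.25 ± 0.05) and Foxp1 (-0.21 ± 0.04) fell and 15 of 18 did not pass, while Foxp1 and Maob were each higher in 3 of the 9 pool pairs. Medians of the striatum list ran from -0.69 to 0.34 over the pool pairs. For Adcy5, Meis2 and Foxp1 unequal tissue in the pools was not told apart from a strain difference. Single members of other lists were the kinase Sik1 (-0.32 ± 0.06), the potassium channel Kcnd2 (-0.19 ± 0.03), the vesicle protein Rab3a (0.19 ± 0.03), the astrocyte marker Acsbg1 (-0.17 ± 0.03), the microglia marker C1qa (-0.18 ± 0.04) and the haemoglobin chain Hbb-b1 (-0.36 ± 0.06). C1qa had an adjusted p of 0.0497 and passed in 6 of 28 alternatives, Sik1 in 13 of 28, and Adcy5, Gabrg1 and Meis2 each in 14 of 28. Acsbg1 passed in 16 of 28 and Ifi27 in 17 of 28. On the arrays with WHP in Cy5 alone Acsbg1 was -0.022, Ifi27 0.17, Maob -0.095 and RT1-M3-1 0.16, and on those with WHP in Cy3 Sik1 was -0.21. Mx2 was -1.07 with the scanner's processed signals. The neuropeptide receptor Npy5r (0.28 ± 0.06) and the proteoglycan Vcan (0.16 ± 0.03) passed too, but turned to -0.12 and -0.054 on the arrays with WHP in Cy3. Values from a single dye orientation hold any dye effect as well. No member of the serotonin, opioid, stress hormone, endocannabinoid, glutamate, ethanol metabolism, antioxidant, cholesterol, circadian clock, heat shock or respiratory chain lists passed over all probes in the mean. By camera 7 of the 33 lists shifted in the mean: striatum markers (median -0.26, adjusted p = 1.07e-05), astrocyte markers (-0.12, 3.46e-04), GABA signalling (-0.06, 0.0037) and immediate early genes (-0.14, 0.024) lower, and histocompatibility genes (0.16, 0.0026), meninges markers (0.36, 0.0026) and choroid plexus markers (0.37, 0.0029) higher. Immediate early genes ranged from -0.55 to 0.43 over the 9 pool pairs. With an estimated correlation the adjusted p of these lists was 0.647 for GABA signalling and 0.789 for the other 6.

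In the mean 810 of 28376 probes passed limma's test, 383 higher and 427 lower, and 5059 had an unadjusted p under 0.05. They stood for 328 named genes by the brightest probe, 135 higher and 193 lower, and their median size was 0.26 log2 units. The count was 1553 and 538 without nucleus accumbens pair 1 or 3, 1308, 491 and 312 without prefrontal pair 1, 2 or 3, and 335, 402 and 347 without hippocampus pair 1, 2 or 3. It was 469 (241 higher, 228 lower) with the scanner's processed signals and 270 without the pairs whose dye-swapped arrays were uncorrelated. It was 1924 with all 18 arrays entered singly, 491 with the replicate number as a block, 295 with 1 probe per gene and 143 with the covariates. With WHP in Cy5 or Cy3 alone it was 1666 and 1226, where a dye effect does not cancel and can add calls.

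The areas shared calls, all of them in the same direction. The nucleus accumbens and the prefrontal medial cortex shared 15 higher and 5 lower probes, against 0.026 and 0.0095 from independent lists. The nucleus accumbens and the hippocampus shared 20 higher and 9 lower probes, against 0.066 and 0.038. The prefrontal medial cortex and the hippocampus shared 14 higher and 5 lower probes, against 0.030 and 0.0095. These expectations leave out that the areas share 1 estimate of each probe's spread, which by itself brings calls together. No probe was called in opposite directions in any area pair. Across all probes the 2 areas' ratios correlated at r = 0.56 (rho 0.50), 0.34 (rho 0.12) and 0.49 (rho 0.25) in the same order, where probes are not independent replicates. The nucleus accumbens and prefrontal pool pairs also shared slides and a scan session, and striatum markers stood at about the same level in both areas. In all 3 areas 16 probes passed, 13 higher and 3 lower, and 8 of them carried a gene symbol. The 68 calls shared by area pairs became 121 with outlying local backgrounds replaced, 26 with 1 probe per gene and 6 without the pairs whose dye-swapped arrays were uncorrelated. They became 24 and 21 without prefrontal pair 2 or 3, and 30, 23 and 18 without hippocampus pair 1, 2 or 3.

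No probe's strain difference itself differed between areas past limma's test. The simulation did not cover these differences, so the size that would pass was not estimated. The absence of calls does not show that the strain differences are equal. For the nucleus accumbens minus the prefrontal medial cortex 0 of 28501 probes passed and 948 had an unadjusted p under 0.05. The smallest p-values belonged to Foxp1 (-0.56 ± 0.09), Cyld (-0.46 ± 0.08), Arpp21 (-0.73 ± 0.13), Lcat (1.07 ± 0.20) and Fbxo2 (0.35 ± 0.06), each with adjusted p = 1.00. For the nucleus accumbens minus the hippocampus 0 of 29842 passed and 2574 had an unadjusted p under 0.05, with Rlbp1 (-0.42 ± 0.06), Maob (-0.41 ± 0.06), Coro7 (-0.32 ± 0.05), Cpne5 (-0.30 ± 0.05), Cnmd (-1.92 ± 0.33) and Klhdc2 (0.30 ± 0.05) at adjusted p = 0.58. The count was 5 and 2 without nucleus accumbens pair 1 or 2, 1 without prefrontal pair 1 and 8 with all 18 arrays entered singly. For the prefrontal medial cortex minus the hippocampus 0 of 28587 passed and 1029 had an unadjusted p under 0.05, with B3galt2 (0.60 ± 0.09), Efr3a (0.32 ± 0.05), Coro7 (-0.27 ± 0.05) and Cml3 (-0.62 ± 0.13) at adjusted p = 1.00, and the count was 1 on the arrays with WHP in Cy5. Or10j3b differed by 0.55 and 0.43 from the hippocampus in the nucleus accumbens and the prefrontal medial cortex, and by -0.18 and -1.11 with the scanner's processed signals. The hippocampus arrays made up the second of 2 scan sessions, so that area and session cannot be told apart in these 2 differences.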

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

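Tests chosen only after the result was seen are those of swapped strains, of replaced backgrounds, of second probes, of the Arpp21 probe across areas, of chromosome neighbours and of both explanations for the meninges genes. The test of neighbouring tissue in prefrontal pool pair 1 and the splits of the samples were written before their results were seen.

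Prefrontal pool pair 1 ran against pool pair 2 across probes. Swapped strains are argued against by the 199 probes called from the nucleus accumbens and hippocampus alone, of which 87.9% took their sign in pair 1, beside 97.5% and 95.5% in pairs 2 and 3. The outlying local backgrounds of 1 array are argued against as well, since pairs 1 and 2 still correlated at -0.33 with those replaced. Different shares of neighbouring tissue in the 2 pools remain a candidate explanation: across 26790 uncalled probes outside the lists the ratio of pair 1 correlated at 0.44 with the intensity difference between the prefrontal and the nucleus accumbens arrays, against -0.24 to 0.16 in the other 8 pairs. No biological explanation was tested.

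Strain differences of called probes, in the mean or in an area, could come from sequence variants under single probes rather than from RNA levels. As the whole cause this was set against the other probes of genes called in the mean. Of these, 37.3% had the same sign and an unadjusted p under 0.05, against 12.3% for uncalled genes. That ratio of 3.03 only just met a cut chosen after the result was seen. Called probes of the same gene also count once for each other, so the ratio does not decide the question. For Prim1 a variant is argued against by its second probe, which passed in every area at 0.73 or more. For Arpp21 the called probe stood at -0.057 ± 0.09 in the prefrontal medial cortex and -0.79 ± 0.09 in the nucleus accumbens. This difference did not pass the test between areas, so a variant stays open for Arpp21. It stays open for 6 other named genes whose other probes all lie under 0.2 in size (Appl1, Copg2, Eif4e3, Sult1c2a, Trim16 and Unc5d), where a transcript end used by 1 strain would look alike, and for named genes with 1 probe. Inherited stretches of chromosome may account for part: 52.6% of 631 called loci had another called locus 100000 to 1000000 bases away, a share that 18 of 1000 random draws reached (mean 47.3%, highest 56.3%), so this too stays open. Strain differences in RNA level are the biological explanation that the design names, and remain possible for the same genes.

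Meninges and choroid plexus genes swung between pool pairs. A strain difference carried by every pool is argued against for the meninges list, whose median took both signs among the pool pairs of 3 of 3 areas. Uneven amounts of these tissues carried along at dissection could account for the swings but stay open, since the pairs with a list median of at least 0.5 in size had between 77.8% and 100% of the list's genes on that side and the pools cannot be dissected again. With both lists as covariates the counts fell to 4, 7, 10 and 143 in the nucleus accumbens, the prefrontal medial cortex, the hippocampus and the mean, in a fit with fewer residual degrees of freedom.

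Swapping the strain labels within pool pairs gave other splits of the same samples. In the mean of the areas 1 of 100 splits (a draw from all possible ones, the real one included) gave as many as the 810 calls, the highest of the others 456, so a random grouping of the labels can be excluded there if the areas' pools came from different rats. The labels do not say so, and pools from the same rats would leave too few splits. Within an area only 4 splits exist, too few for a share under 0.05: 2 of 4 reached the 76 calls of the nucleus accumbens (highest other 97), 1 of 4 the 26 of the prefrontal medial cortex (highest other 8) and 1 of 4 the 87 of the hippocampus (highest other 0). For each difference between areas 10 regroupings exist, also too few, and 10 of 10 reached the real count of 0, with highest others of 1, 0 and 0.

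The rule for a sample far from the others flags about 1 in 20 groups of independent values from 1 normal population. The groups here hold dye-swapped arrays of the same pools or pool pairs of different areas, so that rate need not hold. Such a sample was looked for in 78 groups and found in 11. Over the 9 pool pairs, and all genes of a list detected in any area, these were cholesterol synthesis in nucleus accumbens pair 3 (median 0.19, others -0.20 to -0.005), dopamine signalling in prefrontal pair 1 (-0.36, others -0.11 to 0.14), antioxidant enzymes in prefrontal pair 1 (-0.14, others -0.011 to 0.11), neuropeptides and receptors in nucleus accumbens pair 3 (0.18, others -0.06 to 0.04), potassium and calcium channels in prefrontal pair 1 (0.14, others -0.11 to 0.005) and the gene Meis2 in nucleus accumbens pair 2 (-0.72, others -0.34 to -0.07). Over the 6 arrays of an area, the first array of prefrontal pair 1 stood apart in the value table's correlation with the scanner ratios (0.62, others 0.94 to 0.98), in cortex markers (1.32, others 2.61 to 3.02) and in hippocampus markers (0.30, others 1.01 to 1.25). The first array of hippocampus pair 3 stood apart in the same correlation (0.76, others 0.92 to 0.97) and in hippocampus markers (1.60, others 2.05 to 2.21). These are the 2 arrays with the largest outlying local backgrounds.

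Differences of list shifts between areas passed camera with a preset correlation in 22 of 99 tests and in 0 with an estimated correlation (lowest adjusted p 0.83). The median over a list's genes of the nucleus accumbens minus the prefrontal medial cortex was -0.062 for glutamate receptors and transporters, -0.063 for potassium and calcium channels, 0.12 for cholesterol synthesis, 0.78 for meninges, 0.16 for blood cell and -0.39 for striatum markers. Of the nucleus accumbens minus the hippocampus it was 0.10 for neuropeptides and receptors, -0.15 for ribosomal proteins, -0.19 for astrocyte, -0.37 for oligodendrocyte and myelin, -0.10 for microglia, -0.42 for ependyma and choroid plexus and -0.19 for striatum markers. Of the prefrontal medial cortex minus the hippocampus it was -0.068 for ethanol metabolism, -0.19 for histocompatibility and antigen presentation, 0.031 for the respiratory chain, -0.13 for ribosomal proteins, 0.15 for neuron, -0.20 for astrocyte, -0.23 for oligodendrocyte and myelin, -0.10 for microglia and -0.26 for blood cell markers.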

How the results depend on the processing

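Every named gene of an area kept its direction under every alternative run for it, while sizes and the number of calls did not hold. Counts are given below in the order nucleus accumbens, prefrontal medial cortex, hippocampus and mean of the areas, against 76, 26, 87 and 810, where they moved by over 1.5 times. Leaving out pool pairs 1 by 1 gave 23 to 725, 1 to 36, 9 to 103 and 312 to 1553, with 0 to 5 for the nucleus accumbens minus the hippocampus and 0 for the other 2 differences, 18 to 85 shared calls (68) and 17 to 39 list shifts (22). With a pool pair left out, its area kept 2 pairs and drew its spread from all areas. The cause was not tested where none is named.

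With the scanner's processed signals the last 3 counts were 71, 21 and 469, and the Or10j3b differences of the nucleus accumbens and the prefrontal medial cortex from the hippocampus reversed to -0.18 and -1.11. Sizes grew by over 1.5 times with these signals for Uros (1.13, 1.17 and 0.76 in the 3 areas, 1.02 in the mean), Trim16 (-2.73) and Sult1c2a (1.53). They also grew for Mx2 (-1.16 in the nucleus accumbens, -1.13 in the hippocampus, -1.07 in the mean), Or10j3b (-1.23 in the hippocampus) and Or5b123b (-3.51 and -3.97 in the first 2 areas). Over all alternatives the Rlbp1 difference of the nucleus accumbens from the hippocampus ran from -0.99 to -0.35. Without background subtraction the prefrontal count was 62, with the deposited value table the hippocampus count 26, and with a trend over intensity and robust eBayes the nucleus accumbens count 116. Each area fitted alone, with 2 residual degrees of freedom, gave 3, 1 and 19. All 18 arrays with a dye covariate and pool pair as a random block gave 807, 145, 357 and 1924, and 8 for the nucleus accumbens minus the hippocampus. With a single dye orientation a dye effect does not cancel, so the next values can mix dye and strain differences. The arrays with WHP in Cy5 gave 124, 70 and 1666 (nucleus accumbens, prefrontal medial cortex, mean) and 1 for the prefrontal medial cortex minus the hippocampus. They shrank Zeb2 (0.49), Uros (0.31), Hunk (0.20) and Rpl38 (-0.16) in the hippocampus, Cpne5 (-0.17) in the prefrontal medial cortex, and Acsbg1 (-0.022), Ifi27 (0.17), Maob (-0.095) and RT1-M3-1 (0.16) in the mean. Those with WHP in Cy3 gave 14, 2 and 1226, and Npy5r and Vcan reversed in the mean to -0.12 and -0.054, while Mrpl4 in the prefrontal medial cortex and Sik1 in the mean shrank to -0.20 and -0.21. A log2 ratio of at least 1 left 11, 5, 14 and 15, and 1 probe per gene, which tests fewer probes, 24, 13, 19 and 295 with 26 shared calls.

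With the replicate number as a block the counts were 11, 3, 19 and 491. The number ties nucleus accumbens and prefrontal pools to a shared slide, but not to shared deviations: of 9 same-numbered pairs across areas 2 had deviations that correlated over 0.1 (-0.38 to 0.17), and 2 of 9 pool pairs correlated best with their own number.

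Of the settings chosen after seeing the data, replaced local backgrounds gave 53 prefrontal calls and 121 shared calls, and pool pairs with uncorrelated dye-swapped arrays left out gave 2, 8, 2 and 270 with 6 shared calls. The first scan session alone gave 5 and 1, and 1 and 1 with slide as a fixed block. Meninges and choroid plexus covariates gave 4, 7, 10 and 143.

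Of the list shifts 0 remained with an estimated correlation and 0 with fry. In the prefrontal medial cortex the ribosomal list reversed to 0.030 without prefrontal pair 1 and stood at -0.069 without pair 2, and the ependyma and choroid plexus list reversed to -0.097 without pair 2 and stood at 0.862 without pair 1. Medians shrank by over 1.5 times without pair 2 of the nucleus accumbens for its glutamate (-0.021), meninges (0.23) and striatum (-0.26) lists and without pair 3 for its ribosomal list (-0.021). They shrank without prefrontal pair 1 for its astrocyte list (-0.081), without hippocampus pair 1 for its histocompatibility (0.10), interferon (0.010), choroid plexus (0.30) and meninges (0.18) lists, and without hippocampus pair 3 for its neuron list (-0.018). They grew without pair 1 of the nucleus accumbens for its glutamate (-0.13) and ribosomal (-0.065) lists, without pair 2 for its astrocyte list (-0.20, and -0.21 with the mean over a gene's probes) and without pair 3 for its meninges list (1.60). They grew without prefrontal pair 1 for cholesterol (-0.13) and pair 3 for blood cells (-0.17), and without hippocampus pair 1 for the thalamus list (-0.19), pair 2 for neurons (-0.15) and meninges (0.58) and pair 3 for interferon (0.11). The processed signals gave -0.20 for prefrontal blood cells and -0.09 for GABA in the nucleus accumbens and the hippocampus. Over all 22 list shifts, 179 values kept direction and call with a pool pair left out, 17 lost the call and 2 reversed, against 120 that kept the call and 56 that lost it under other settings. Named genes kept direction and call in 414 of the values with a pool pair left out and lost the call in 315, and in 1075 and 580 of the values under other settings. Scaling between arrays, leaving out saturated spots and leaving out population outliers changed no count of calls: the first leaves ratios as they are and no spot was saturated. Detection filters, slide as a random block and the mean over a gene's probes moved no count they were run on by over 1.5 times. Dim probes are limited by signal over background, with 28376 of 41012 probes detected in all 3 areas.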

Other observations

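Other named genes differed in the mean of the areas and were picked here after their values were seen. Both probes of Fam111a were lower in WHP (-1.38 ± 0.18 and -0.93 ± 0.13), and Retsat (-0.86 ± 0.11), Eid1 (-0.87 ± 0.10) and Rabif (-0.77 ± 0.12) were lower too, although another Eid1 probe stood at -0.01. The sodium channel gene Scn9a was higher at 0.94 ± 0.06, with 0.66 in the nucleus accumbens, 0.99 in the prefrontal medial cortex and 1.16 in the hippocampus, while its other probe stood at 0.17 without passing, and Pbld1 (1.16 ± 0.16) and Zscan25 (1.56 ± 0.30) were higher as well. The strongest probe of all had no gene name and no rn4 position: A_44_P551963 was higher by 3.06 ± 0.07, with 2.98, 3.14 and 3.07 in the 3 areas.

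With outlying local backgrounds replaced, 6 genes were added and 1 lost in the prefrontal medial cortex, 10 added and 2 lost in the hippocampus, and 3 added and 4 lost in the nucleus accumbens. In the mean of the areas 21 were added and 46 lost. Mrpl52 was lost in all 3 areas (-0.57 ± 0.12, -0.68 ± 0.12 and -0.53 ± 0.12, adjusted p = 0.12, 0.096 and 0.19 by limma), Copg2 (-0.59 ± 0.11) in the hippocampus, and Grem1 (0.95 ± 0.17), Pik3c3 (0.32 ± 0.05) and Trmt11 (-0.29 ± 0.05) in the nucleus accumbens. In the prefrontal medial cortex Unc5d (-1.07 ± 0.13), Mx2 (-0.50 ± 0.06), Or10j3b (-0.42 ± 0.06) and Cby2 (-0.37 ± 0.05) were lower and Mrpl43 (0.39 ± 0.05) and Tmem68 (0.36 ± 0.05) higher. In the hippocampus Fam111a (-1.93 ± 0.28), Trim16 (-1.24 ± 0.17), Tpd52l1 (-1.19 ± 0.19), Tmem30b (-0.65 ± 0.10) and the interneuron transcription factor Dlx1 (-0.42 ± 0.07) were lower, and Pbld1 (1.89 ± 0.28), Nr2c1 (0.62 ± 0.09), Sgcb (0.43 ± 0.06), Lat (0.39 ± 0.06) and Tmprss3 (0.27 ± 0.04) higher. In the nucleus accumbens Lat (0.40 ± 0.06) and Ttc8 (0.34 ± 0.05) were higher and Nherf1 (-0.29 ± 0.04) lower.

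The probes called in the mean gathered in some stretches of the genome. Of 553 windows 7 passed a test of the number of called loci against the genome's share (hypergeometric, Benjamini-Hochberg), chosen after the calls were seen. The clearest lay on chromosome 19 between 20000001 and 25000000, with 14 called of 59 loci where 2.31 would be the share (adjusted p = 2.45e-05), and 12 of the 14 were higher in WHP. The test treats loci as independent, but overlapping probes can count as separate loci. Examples are A_44_P157024 (24482319 to 24493681) and A_44_P361327 (24493670 to 24493729), so the p-value overstates the independent evidence. Neto2 (-0.32 ± 0.04) and Gadd45gip1 (0.17 ± 0.04) lie there among unnamed probes such as A_44_P330847 (0.73 ± 0.08). On chromosome 10 between 45000001 and 50000000 there were 12 called of 85 loci, with Trim16 (-1.12 ± 0.10), Tvp23b (0.36 ± 0.06) and Mief2 (-0.18 ± 0.02). On chromosome 1 between 185000001 and 190000000 there were 13 of 98, with Lat (0.33 ± 0.04) higher and Ino80e (-0.48 ± 0.05), Asphd1 (-0.30 ± 0.05) and Bcl7c (-0.28 ± 0.03) lower.

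Probes placed on the mitochondrial genome were frequent among the calls, and a strain difference in mitochondrial DNA is a candidate explanation, tested after the calls were seen. Of 46 such probes 12 passed in the mean (26.1%, against 2.82% of the other probes, one-sided Fisher's exact test p = 4.31e-09), 6 higher and 6 lower. Probes close together went opposite ways: A_44_P463065 at 7525 to 7584 stood at 1.08 ± 0.05 and A_44_P463064 at 7585 to 7644 at -0.27 ± 0.05. Neighbouring probes share transcripts, so the count overstates the independent evidence, and the arrays hold no sequence that would show whether variants exist under these probes.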
